A study of Prunus cerasifera with 12 samples.

How the data were processed

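Poly(A) RNA from roots of 2 accessions of Prunus cerasifera, untreated or 48 h after inoculation, was sequenced as stranded paired-end libraries, 3 biological replicates in each of 4 groups. Plantlets raised in vitro had spent 3 weeks in perlite at 24 °C and 1 week in sandy soil in 50 ml tubes. Groups were taken from the sample labels, and replicate status from the series design text.

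Per the submitters' processing notes the tools were HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.8 and DESeq2. The role of each aligner, the DESeq2 version, the genome build, the annotation and the strand setting are not given in the sources used here. One table deposited by the authors gives an estimated count of reads per gene and library, made before deposition with RSEM named among the tools and not normalized. Between 89.6% and 90.1% of these values per library were whole within 0.005. The same deposited table gives FPKM, which per the file headers is also given as group means, and TPM, which the authors scaled to the same sum in each library. A second table from the authors gives, per the file headers, a log2 fold change for each of 4 comparisons. It also holds the authors' DESeq2 p-values and q-values, whose adjustment is not given in the sources used here. The sign of the authors' fold change was checked against the mean counts and follows the second-named group over the first.

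Estimated counts were rounded to whole numbers. In R 4.3.3 with edgeR 4.0.16, genes were kept by filterByExpr over the 4 groups (minimum count 10, minimum total 15), which left 17789 of 20502 genes and at least 99.98% of the counts of each library. Libraries were scaled by TMM (factors 0.983 to 1.02). A quasi-likelihood model (glmQLFit, robust) with 1 coefficient per group was fitted to all 12 libraries, and 5 contrasts were tested: inoculated against untreated in each accession, the difference between these responses, and resistant against susceptible in each treatment. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 within each contrast, all tests being two-sided. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled totals, and log2 CPM for principal components and correlations used a prior count of 2. Expected overlaps assume independent lists among the tested genes. The 2 responses share no library, nor do the 2 accession comparisons. All contrasts share each gene's estimate of spread, so lists can overlap beyond the independent value without a shared response.

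Choices made before the data were examined were the groups, contrasts, tests, most alternatives and the rule for named genes. The rule took the genes with the largest fitted rise and fall among those with an adjusted p below 0.05, a mean log2 CPM of at least 1, no overlap of replicates between the groups compared (a condition not set for the difference between responses) and an informative description. The files pair no descriptions with the gene symbols, so that last condition could not be applied, and 2 genes per direction and contrast are named in place of the larger number planned. For the same reason none of the 47 gene lists fixed beforehand could be matched, and no gene list was tested.

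Library totals of 18168664 to 20955128 counts set the precision. Where a group had 0 counts, a fold is a lower bound against 3 counts per library. With 1 to 3 counts it is a ratio with a 95% Clopper-Pearson interval. Both cover counting error only, and reads are not known to be independent molecules. The test was tested on simulated data with the spread of these libraries. Of 17789 genes, 100 were changed by each amount, and genes with low counts were not chosen for change. This is a smaller share than was called in the real contrasts, so the recovery there can differ. In the susceptible contrast it recovered 76% of genes changed by 0.5 on the log2 scale and 97% of those changed by 1, and 17 of 190 calls were unchanged genes. In the resistant contrast it recovered 60% and 98%, and 12 of 170 calls were unchanged genes.

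The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors or upper-quartile scaling in edgeR, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, limma 3.58.1 on log2 FPKM or TPM with a pseudocount of 1 or 0.1, a replicate number as a block, only the compared groups in the fit, a log2 fold change of at least 1, and each library left out in turn. Chosen after seeing the data were genes with whole counts only, libraries thinned to the lowest total, a length trend (lowess, span 0.3) removed from each library, and an adjusted p below 0.01. Replicate pairs were checked for duplicated libraries: chi-square per gene was 3.65 to 9.33, above the 1 that sampling noise alone gives. The authors' group means were not used in any test.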

Results

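Root transcripts were measured in 2 accessions of Prunus cerasifera, the cherry plum or Myrobalan plum, a rootstock species. Accession P. 2175 carries Ma, a gene for resistance to root-knot nematodes, in the heterozygous state (Ma/ma), and is called resistant here. Accession P. 2032 (ma/ma) lacks it and is called susceptible. Plantlets were left untreated or were inoculated with about 15000 second-stage juveniles of Meloidogyne incognita. Juveniles of this root-knot nematode enter roots and set up feeding sites. Inoculated roots were taken after 48 h. The labels give no time for untreated roots, so handling and harvest time were not separated from the nematodes in the changes below. Each of the 4 groups had 3 biological replicates, giving 12 RNA-seq libraries. Library totals ran from 18168664 to 20955128 estimated read counts. The mean total was 19621133 ± 9658 counts (SD, n = 3) in untreated susceptible roots and 19014022 ± 765632 counts (SD, n = 3) in inoculated susceptible roots. In the resistant accession it was 20321516 ± 689774 counts (SD, n = 3) untreated and 19387216 ± 358776 counts (SD, n = 3) inoculated. Of 20502 genes in the table, 17789 had enough counts to be tested, with a median of 398 counts per gene and library. A count of 0 allows up to 3 counts in a library, which is 0.141 to 0.166 CPM (counts scaled by library size). Such limits cover counting error only. Genes are given by the symbols in the files, which carry no descriptions, so the genes named below have no stated function.

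The accessions differed more than the treatments did. Across genes, log2 CPM of 2 libraries of the same group correlated at 0.992 to 0.994, libraries of the 2 treatments of one accession at 0.982 to 0.990, and libraries of different accessions at 0.938 to 0.946. Genes are not independent replicates, so these values describe similarity only. The first principal component held 72.1% of the variance and separated the accessions. The second held 9.40% and separated treated from untreated resistant roots. It also separated the susceptible treatments, by less and in the same direction. The third held 5.36% and separated treated from untreated susceptible roots. It also separated the resistant treatments, by less and in the opposite direction. Each of the 12 libraries correlated best with a library of its own group. The biological coefficient of variation was 6.30%.

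**Figure D1:**
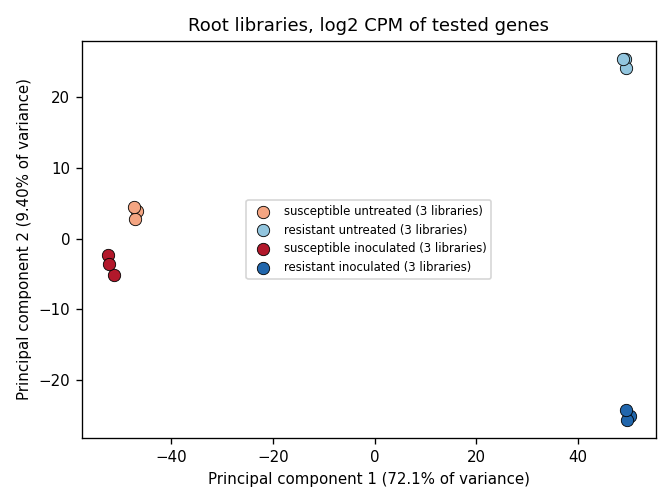
First (horizontal) and second (vertical) principal components of log2 CPM over the 17789 tested genes, 1 point per library, 3 libraries per group. The first component (72.1% of the variance) parts the accessions, and the second (9.40%) parts the resistant treatments by more than the susceptible ones.

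In susceptible roots, inoculation changed 2079 genes (11.7% of those tested), of which 1185 rose and 894 fell. Most changes were small, with a median fold of 1.31. A change of at least 2-fold was reached by 126 genes that rose and 54 that fell. The genes that rose took 8.15 ± 0.0463% of all counts before and 10.8 ± 0.128% after inoculation (SD, n = 3). Those that fell went from 13.8 ± 0.213% to 11.2 ± 0.442% (SD, n = 3). Because the genes were chosen by this test, these shares give only the size of the change. LOC18784824 rose from 1.79 ± 0.371 to 18.7 ± 2.36 CPM (SD, n = 3), a log2 fold change of 3.38 (SE 0.17, edgeR adjusted p = 2.57e-13). LOC18786412 rose from 2.04 ± 0.700 to 19.4 ± 1.41 CPM (SD, n = 3), or 3.24 on the log2 scale (SE 0.18, edgeR adjusted p = 1.64e-11). LOC18771380 fell from 22.4 ± 0.856 to 2.72 ± 0.343 CPM (SD, n = 3), a log2 fold change of -3.04 (SE 0.13, edgeR adjusted p = 2.84e-14). LOC18778495 went from 4.46 ± 1.09 to 0.650 ± 0.854 CPM (SD, n = 3), a log2 fold change of -2.77 (SE 0.57, edgeR adjusted p = 0.0126). Its inoculated libraries differed widely, at 0.332, 1.62 and 0 CPM, though all lay below the untreated ones, and its estimated counts were not whole numbers, as happens when reads are divided between similar genes. Its log2 fold change was -4.77 without inoculated replicate 2 and -2.16 without inoculated replicate 3. Without inoculated replicate 1 its edgeR adjusted p was 0.0587, and over all alternatives tried it ran from 1.39e-06 to 0.0667. The excess of genes that rose over genes that fell was lost under upper-quartile scaling, which gave 1047 higher and 1073 lower. Of these 2120 genes, 1940 were also called in the reported test. Limma on log2(TPM + 1) gave 1315 higher and 660 lower. The authors' deposited DESeq2 table held 1589 genes at q below 0.05 for this comparison, and 1509 of these were also called here, all in the same direction.

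In resistant roots, inoculation changed 5212 genes (29.3%), of which 2645 rose and 2567 fell. The median fold was 1.30. At least a 2-fold change was reached by 361 genes that rose and 147 that fell. The genes that rose went from 19.2 ± 0.0970% to 25.4 ± 0.159% of all counts (SD, n = 3), and those that fell from 22.3 ± 0.0346% to 17.2 ± 0.0456% (SD, n = 3). LOC18786629 rose from 5.57 ± 0.767 to 35.4 ± 5.36 CPM (SD, n = 3), a log2 fold change of 2.67 (SE 0.16, edgeR adjusted p = 1.44e-08). Its estimated counts were not whole in these libraries. LOC18793637 rose from 0.975 ± 0.0398 to 5.85 ± 1.47 CPM (SD, n = 3), or 2.58 on the log2 scale (SE 0.21, edgeR adjusted p = 8.20e-10). LOC18767441 fell from 11.7 ± 0.976 to 2.44 ± 0.326 CPM (SD, n = 3), a log2 fold change of -2.27 (SE 0.14, edgeR adjusted p = 8.58e-12). LOC109947185 had 2, 1 and 2 counts in the untreated libraries and 0 in each inoculated library. Both groups lay at or under the limit that a count of 0 allows, so no fold is given. Its edgeR adjusted p was 0.0437, and over the alternatives tried it ran from 0.000143 to 0.255. With limma on log2(TPM + 1), which changes the test, the filter and the unit together, 2039 genes were higher and 3379 lower. Other scalings within edgeR gave 2696 higher and 2462 lower (DESeq2 size factors) and 2600 higher and 2644 lower (upper quartile). The authors' deposited table held 4257 genes at q below 0.05, of which 4130 were also called here, all in the same direction.

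**Figure D2:**
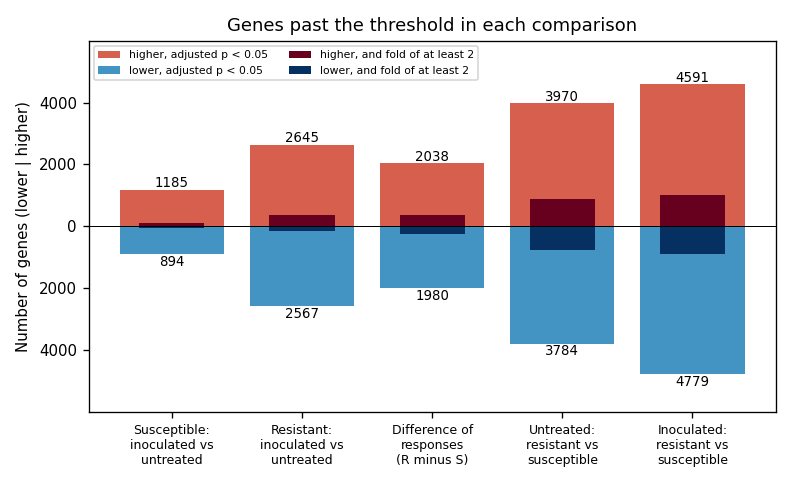
Genes higher (bars above 0) and lower (bars below 0) in each comparison at an edgeR adjusted p below 0.05, out of 17789 tested, with those changed at least 2-fold as narrow dark bars. Inoculation changed 2079 genes in susceptible and 5212 in resistant roots, and the accessions differed in 7754 genes untreated and 9370 inoculated.

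Whether the accessions responded differently was tested as the difference between their responses, resistant minus susceptible. This difference was called for 4018 genes (22.6%), with 2038 shifted upward and 1980 downward in the resistant accession relative to the susceptible one. The difference was at least 2-fold for 617 of them, 377 upward and 240 downward. LOC18786629, which rose in resistant roots, fell in susceptible roots from 37.0 ± 6.02 to 13.6 ± 2.08 CPM (SD, n = 3), and the difference was 4.12 on the log2 scale (SE 0.22, edgeR adjusted p = 8.36e-09). LOC18771380, which fell in susceptible roots, stood at 0.522 ± 0.132 CPM in untreated and 0.802 ± 0.233 CPM in inoculated resistant roots (SD, n = 3), a difference of 3.65 (SE 0.35, edgeR adjusted p = 4.10e-08). LOC109947317 rose in susceptible roots from 0.511 ± 0.271 to 3.51 ± 1.05 CPM (SD, n = 3). In resistant roots it fell from 13.6 ± 1.196 to 9.93 ± 0.848 CPM (SD, n = 3), a difference of -3.23 (SE 0.33, edgeR adjusted p = 2.07e-07). LOC109947185 went from 3.17 ± 0.498 to 5.20 ± 0.232 CPM in susceptible roots (SD, n = 3) against at most 2 counts per library in resistant roots. Its difference had an edgeR adjusted p of 0.0236, with a range of 0.000106 to 0.0557 over the alternatives tried. On log2(TPM + 1) with limma, the differences divided into 1426 higher and 2978 lower, where the count-based test had near-equal numbers. This comparison is not among the 4 of the authors' table.

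Both responses passed the threshold for 1055 genes, and 653 of these changed in the same direction. In detail, 374 genes rose in both accessions, where 176 would be shared if the lists were independent, and 279 fell in both, against 129. Another 402 genes changed in opposite directions. Of these, 198 rose in susceptible and fell in resistant roots (171 if independent), and 204 did the reverse (133 if independent). The difference between the responses was called for all 402, which their selection all but fixes. Among the 653 genes that moved the same way, the difference was called for 182, of which 133 had the larger change in resistant roots and 49 in susceptible roots. A further 4157 genes passed in the resistant accession and not in the susceptible one. For 2406 of these the difference was called, and for 1751 a differing response was not shown. Of the 1024 genes that passed in the susceptible accession and not in the resistant one, the difference was called for 574. At a change of at least 2-fold in both accessions there were 38 genes, of which 28 moved the same way. Across the 17789 genes the 2 responses had a Pearson r of 0.0770 and a Spearman rho of 0.0115, and genes are not independent replicates.

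**Figure D3:**
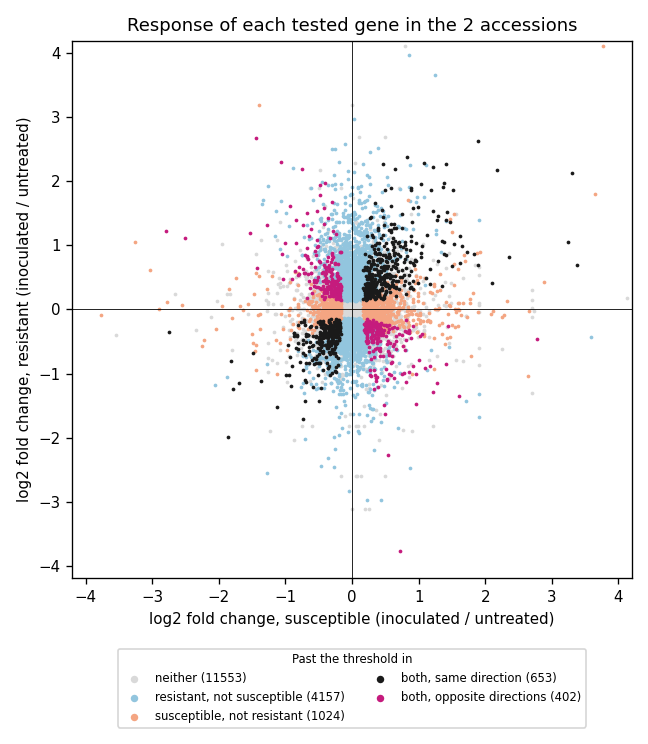
Fitted log2 fold change after inoculation of each tested gene in susceptible (horizontal) and resistant (vertical) roots, coloured by whether it passed an edgeR adjusted p below 0.05 in each accession, with 5 genes outside the axes. The 653 genes changed in the same direction and the 402 changed in opposite directions lie in separate quadrants, and most called genes (4157) passed in resistant and not in susceptible roots.

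Untreated roots of the 2 accessions differed in 7754 genes (43.6%), with 3970 higher and 3784 lower in the resistant accession. The median fold of these was 1.40, and the difference was at least 2-fold for 877 genes higher and 774 lower. LOC18788042 had 544 ± 29.8 CPM (SD, n = 3) in resistant roots and 0 counts in every susceptible library, so it was at least 3547-fold higher against the limit of 3 counts per library (edgeR adjusted p = 4.00e-20). LOC18778998 had 44.9 ± 0.916 CPM (SD, n = 3) against 0 counts, at least 293-fold higher (edgeR adjusted p = 1.47e-19). LOC18784233 had 115.6 ± 2.46 CPM (SD, n = 3) in susceptible roots and 0 counts in resistant roots, at least 791-fold lower in the latter (edgeR adjusted p = 1.86e-22). LOC18779384 had 13.4 ± 0.599 CPM (SD, n = 3) in susceptible roots against 0 counts, at least 91.3-fold lower (edgeR adjusted p = 9.26e-16). The estimated counts of LOC18788042 and LOC18779384 were not whole numbers. A transcript whose sequence differs from the reference can lose reads, and no count here separates that from a lack of the transcript. The authors' deposited table held 6948 genes at q below 0.05, of which 6710 were also called here, all in the same direction.

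After inoculation the accessions differed in 9370 genes (52.7%), with 4591 higher and 4779 lower in resistant roots. The median fold was 1.39, and the difference was at least 2-fold for 1023 genes higher and 876 lower. LOC18788042 stood at 448 ± 44.8 CPM (SD, n = 3) in resistant roots against 0 counts, at least 2842-fold higher (edgeR adjusted p = 4.25e-20). LOC18768444 had 19.0 ± 2.03 CPM (SD, n = 3) against 0 counts, at least 121-fold higher (edgeR adjusted p = 5.72e-16). LOC18781996, with estimated counts that were not whole, had 48.2 ± 11.6 CPM (SD, n = 3) in susceptible roots and 0 counts in resistant roots, at least 308-fold lower (edgeR adjusted p = 2.66e-09). LOC18784233 had 103.4 ± 4.31 CPM (SD, n = 3) in susceptible roots and 1 count in total over the 3 resistant libraries, a ratio of 5961 with a 95% counting interval (exact Clopper-Pearson) of 1069 to 235475. That count came from inoculated replicate 2, without which the fitted log2 fold change went from -12.09 to -13.98, and both fitted values depend on the prior count. With limma on log2(TPM + 1), 3718 genes were higher and 5565 lower. The authors' deposited table held 8050 genes at q below 0.05, of which 7841 were also called here, all in the same direction.

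The accession difference passed the threshold in both treatments for 5495 genes. In 5030 of these (91.5%) the direction was the same, with 2546 higher and 2484 lower in resistant roots. The other 465 genes crossed, and that the difference between responses was called for all of them nearly follows from this selection. Of the crossing genes, 288 were lower in untreated and higher in inoculated resistant roots. Among these, 272 rose in resistant roots, 94 fell in susceptible roots and 79 did both. The other 177 crossed the reverse way, and 157 of them fell in resistant roots, 86 rose in susceptible roots and 66 did both. A 2-fold difference in each treatment was reached by 7 crossing genes.

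**Figure D4:**
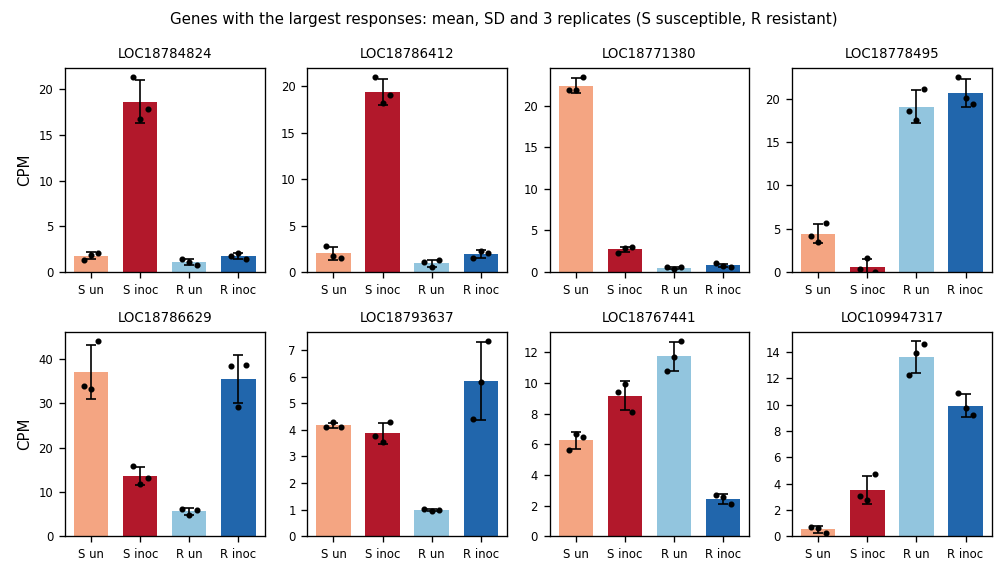
Mean CPM (bars) with SD (error bars) and the 3 replicates (points) of 8 genes named for the responses, in untreated and inoculated roots of each accession. LOC18786629 falls from 37.0 to 13.6 CPM in susceptible roots and rises from 5.57 to 35.4 CPM in resistant roots.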

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

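Of the tests in this part, those chosen only after the result was seen were the match of libraries to groups and the alternatives that thinned the libraries, removed a length trend or kept genes with whole counts.

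The responses of the accessions differed by a test of the difference itself for 4018 genes. Among the genes named in the report, this difference (resistant minus susceptible, log2) was called for 9, of which 4 were named for it and the others for a large change in 1 accession. It was -2.68 for LOC18784824 (SE 0.32), -2.19 for LOC18786412 (SE 0.37), 3.65 for LOC18771380 (SE 0.35), 2.89 for LOC18778495 (SE 0.64) and 4.12 for LOC18786629 (SE 0.22). It was 2.69 for LOC18793637 (SE 0.28), -2.81 for LOC18767441 (SE 0.19) and -3.23 for LOC109947317 (SE 0.33). For LOC109947185 the fitted difference was -4.49, a value that depends on the prior count because its resistant libraries had 2 counts or fewer. Of 100 relabellings of treatment drawn within the accessions, the real one included, 1 called as many genes as the real labels (4018). The highest of the others called 3190, which argues against labels unrelated to expression in both accessions. Most of these relabellings broke up both responses, and some kept the real grouping of 1 accession. As a set they test for no response at all and not for equal responses. In 11 of the drawn relabellings the resistant libraries were grouped as in the real data, with their treatment labels kept or exchanged. These called 1579 to 3190 genes, against at most 137 in the rest, so the high counts follow the resistant grouping. Swapping the treatment labels of the resistant libraries alone called 3828 genes, which tests the sum of the responses and was not among those drawn.

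For the contrasts of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 of them, the real one, gave as many genes in each contrast. The real and the highest other values were 2079 and 0 genes for susceptible roots, 5212 and 1 for resistant roots, 7754 and 0 for untreated roots, and 9370 and 0 for inoculated roots.

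Resistant roots had 2.51 times as many called genes after inoculation as susceptible roots. A difference in depth is argued against, since the ratio was 2.48 with all libraries thinned to the lowest total. A difference in replicate spread is argued against too, since the variance of the log2 changes with replicate noise subtracted had a ratio of 2.36 (2.00 to 2.73 with any 1 library left out). With a length trend removed from each library the ratio of calls was 2.45. These values leave a larger response of the resistant accession as a hypothesis. A shift of the untreated resistant libraries as a group, unrelated to inoculation, could add to the same calls. None of these values separates it from a response (see Other observations). With 1 accession of each kind, an effect of Ma cannot be told from any other difference between them.

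The responses of the accessions were nearly uncorrelated across genes. Replicate noise is argued against as the reason. With it subtracted, the correlation was 0.0812 (0.0410 to 0.116 with any 1 library left out). This used genes with a mean log2 CPM of at least 1. The correction removes spread within groups only, so a shift of a whole group of libraries stays open as a reason. Reads divided between similar genes are argued against by the corrected value over genes with whole counts, 0.0859. In addition, 0 libraries correlated best with a library of another group, which argues against a single library with a wrong label. An exchange of labels between whole groups would leave that match unchanged and was not tested. Accession-specific responses may account for the low value, as a hypothesis found and tested on the same data. Age, handling and any unrecorded difference between the inoculations of the accessions stay open and untested.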

How the results depend on the processing

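Chosen only after the data were seen were the adjusted p below 0.01, whole counts only, thinned libraries and the length trend. No named gene changed direction under the alternatives in which it was tested. The direction that held more of the called genes did change under some alternatives. In susceptible roots it went from 1185 higher and 894 lower to 1047 higher and 1073 lower under upper-quartile scaling. Limma on log2(TPM + 1) turned it in resistant roots and for the difference, as given below. Requiring a log2 change of at least 1 left 180 genes for susceptible roots, 508 for resistant roots, 617 for the difference between responses, 1651 for untreated and 1899 for inoculated roots, since the rule removes small changes. An adjusted p below 0.01 left 1184, 3416 and 2269 genes for the first 3 of these. Every other alternative gave a count within 1.5 times the reported one. With each library left out in turn, the counts were 1405 to 2466 in susceptible roots, 4244 to 4487 in resistant roots, 3258 to 4415 for the difference, 6877 to 7059 untreated and 8410 to 9170 inoculated. The highest susceptible count came without inoculated replicate 2. DESeq2 called 1989, 4858, 3754, 7375 and 8914 genes in the same order. Apart from the rules on fold and on an adjusted p below 0.01, genes called in both accessions in opposite directions numbered 270 to 544. Those in the same direction numbered 481 to 763, and the correlation of the responses was 0.0486 to 0.0903. With a log2 change of at least 1 in both accessions, 10 were opposite and 28 went the same way. Limma on log2(TPM + 1) gave 37.6% of called genes higher in resistant roots against 50.7% reported, 32.4% against 50.7% for the difference (median over all genes -0.11 against -0.03) and 66.6% against 57.0% in susceptible roots. It changes test, filter and unit together. With log2(FPKM + 1) these shares were 44.4%, 44.5% and 57.2%, and the cause was not tested. Of 432 values of named genes under alternatives, 415 kept direction and call and 17 lost the call, all for LOC109947185 and LOC18778495. For LOC109947185, leaving out resistant untreated replicate 1 or 3 or any resistant inoculated replicate gave adjusted p values of 0.0880 to 0.101 for the response and 0.0507 to 0.0557 for the difference. Replicate numbers did not pair the samples: over 18 pairs sharing a title number, residual correlations were -0.0942 to 0.0580, and over 13 sharing a description number -0.0942 to 0.0442. With a block for the description number, 1588 genes were called in susceptible and 4511 in resistant roots. The fit with only the compared groups equals the reported one for the difference, which uses all 4. Tests of gene lists and their alternatives were not run. Depth limits genes near 3 counts per library.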

Other observations

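Of the tests in this part, the slope in resistant roots and its reading as a group shift, and the search for genes at 0 counts in 1 accession, were chosen only after the data were seen.

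Genes at 0 counts in all 6 libraries of one accession and at 10 or more in all 6 of the other numbered 40. Of these, 16 were detected in resistant and 24 in susceptible roots. After inoculation 4 of the 16 changed in resistant roots, 3 higher and 1 lower, and 0 of the 24 changed in susceptible roots by edgeR. At an unadjusted p below 0.05 the numbers were 5 and 5, and DESeq2 called 4 and 0. Over all tested genes, edgeR called 29.3% in resistant and 11.7% in susceptible roots. The difference between the shares of the 16 and of the 24 genes was not tested. Estimated counts that were not whole occurred in 14 of the 40 (35.0%), against 11.9% of 17201 genes with at least 10 counts in every library of an accession.

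Expression in inoculated resistant roots may have shifted in the direction of untreated susceptible roots. The response and the accession gap share the untreated resistant libraries, so the covariance that sharing creates was subtracted, and the slope of the gap on the response was 0.449 (0.430 to 0.466 with any 1 library left out), which is consistent with such a shift across genes. A shift of the untreated resistant libraries as a group, unrelated to inoculation, would give a slope near 1 if it were the whole response, and as a part of it cannot be told apart from the same 0.449, since no other untreated resistant libraries were analysed. In susceptible roots the slope towards untreated resistant roots was -0.119 (-0.186 to -0.0791), which argues against the mirror movement.

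Among genes with a mean log2 CPM of at least 1 that changed at least 2-fold in resistant roots, 256 of 350 (73.1%) moved to the side on which untreated susceptible roots lay, and 137 (39.1%) ended nearer to that level. In susceptible roots 39 of 89 (43.8%) moved to the side of untreated resistant roots and 25 (28.1%) ended nearer. These genes were chosen by their response, which shares the untreated libraries with the gap, and no value without movement was computed, so the shares decide nothing.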
